A study of Danio rerio with 11 samples.

How the data were processed

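Polyadenylated RNA was sequenced from zebrafish eyes, retinae and heads in 11 libraries. RNA had been pooled before extraction from many larval eyes, from several adult retinae or from heads, per the labels' protocols, so each library averages several animals. The larval eyes came from fish carrying a mutation in the eMIC domain of srrm3 and from their wild-type (WT) siblings, with 1 library per genotype at 48, 60 and 72 hours post fertilization (hpf) and at 5 days post fertilization (dpf). A WT head library at 24 hpf and 2 WT adult retina libraries completed the set. The 5 dpf and adult libraries were labelled as stranded and prepared with a different RNA kit from the 48 to 72 hpf libraries, per the labels' protocols. Stage and library set therefore cannot be told apart for 5 dpf and adult against the earlier stages, while each sibling pair lies within 1 set. Nothing in the labels states that the adult replicates came from separate animals, so p-values that rest on them do not measure the spread between animals.

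The deposited values of each library were a whole-number read count per gene and a cRPKM, a length- and depth-scaled value of the RPKM kind. Both were made by the authors on genome build danRer10, per the submitters' processing notes. The aligner, the counting program, their versions, and the correction that the letter c stands for are not given in the sources used here. Each library listed 31848 Ensembl gene identifiers, of which 2461 had no value in any library and 29387 were used. Dividing the deposited counts by the deposited RPKM values gave the same gene length in every library to within 0.106% at the 99th percentile over genes, once library totals were taken into account. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart. Near-identical paralogs, such as the crygm2d lens crystallins, the globins and the digestive proteases, are uncertain as single genes because their reads could be shared. Only gene-level values were analysed here, and the inclusion of microexons, short exons whose splicing the eMIC domain regulates, was not analysed here.

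Gene symbols were taken from a table of gene names, which gave 25682 of the genes with values (87.4%) a symbol, many in the human form. A symbol carried by more than 1 measured gene, as for 4036 genes, is printed with its identifier. RefSeq annotation of assembly GRCz12tu served only to find which genes neighbour srrm3, and no coordinate from it is printed.

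The tests were run in R 4.3.3 on the deposited counts with edgeR 4.0.16: TMM normalization, filterByExpr, robust quasi-likelihood fits, and Benjamini-Hochberg adjustment with a threshold of 0.05. The genotype effect was fitted over the 8 larval eye libraries with stage as a factor, so that siblings were compared within stage, with 3 residual degrees of freedom. The change of the genotype effect with age added a genotype by log2 hours term, with 2 residual degrees of freedom. Developmental change was fitted as a slope per doubling of age with genotype as a term, with 5 residual degrees of freedom. The sibling libraries of an age entered it as independent, though they share a stage and a library set, so its p-values can be too small. Adult retina was compared with 5 dpf WT eyes in a fit over all 11 libraries with 4 residual degrees of freedom. Its spread was pooled over the sibling pairs and the adult pair. Most of it is therefore the variation of the genotype difference between stages, and only the rest is the difference between the adult libraries. In that last fit the 5 dpf level was estimated from both 5 dpf libraries and a shared genotype term, so the fitted change of a gene that differed between genotypes at 5 dpf can depart from its plain adult to WT ratio. Single sibling pairs, and the head against the 48 hpf WT eyes, were compared without a test, as log2 ratios of cRPKM with a pseudocount of 1. Fold changes on that scale understate the change of genes with low values. Genes were counted as 2-fold different when the higher library had a cRPKM of at least 5. Errors are standard errors (SE) unless given as SD. For edgeR they were derived as the absolute log2 change divided by the square root of the test's F, so they are approximate. They can understate the uncertainty of genes with counts near 0.

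A set of 27 gene lists, covering retinal cell classes, stress and immune responses, ribosomal proteins and tissues that could be carried over with an eye, was tested with limma 3.58.1. camera was run with a preset inter-gene correlation of 0.01 and again with a correlation estimated for each list, and fry was run on the same fits. fry asks whether the genes of a list move on balance one way and does not compare the list with other genes. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. In single pairs a list's median was compared with 10000 random lists of the same size matched on mean expression in 20 bins, which describes those libraries and is no test of genotype. Symbols matched the measured genes without regard to case, then without a trailing copy number, then without an a or b suffix, and that matching rule was written from names alone after the data had been opened. Of 823 list symbols 74 matched no gene, among them 12 of 27 for blood and 11 of 53 for the circadian clock.

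The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named srrm3 and srrm4. For each tested comparison it named the genes with the largest significant change either way at a mean cRPKM of at least 1, up to 12 each way for genotype and 6 for the others. Where fewer than 5 passed, it named the 5 with the lowest p that had the same sign in all 4 pairs. It also named up to 2 members of a described list with the largest rise, 2 with the largest fall and 4 past the threshold, and for each single pair the 5 largest ratios either way. Which lists are described with example genes was chosen after values had been seen, and the others are given by medians or counts. A few genes that the rule names are not reported here. Lists of pancreas, liver, intestine, brain region and trunk Hox genes were added after the data had been seen, as were the comparison of the adult replicates by list, fits without the 5 dpf mutant library and list tests of age terms without the 5 dpf pair. DESeq2 1.42.0, limma on log2 cRPKM, other size factors, other filters, other time scales and fits without single libraries or pairs were the alternatives. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

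Each tested comparison was first run on simulated counts with the real means, depths and spread, in which sets of genes changed by known amounts. Genes with low mean counts were left out of the changed sets, so these rates do not describe them. The simulated genotype change was the same at every stage, and changes with age were linear in log2 hours. The rates therefore do not describe a genotype difference confined to a single stage. For the genotype effect 51 of 67 genes changed by 1 log2 unit were found, 66 of 67 changed by 2 and 66 of 66 changed by 4, with 40 calls among 21599 unchanged genes. The change of the genotype effect with age gave 23 of 67, 61 of 67 and 65 of 66, with 34 false calls. In both of these fits false calls were a larger share of all calls than the nominal 0.05. Their adjusted p-values were thus too lenient in this check. The developmental slope gave 14 of 67, 52 of 67 and 65 of 66, and the adult comparison 0 of 67, 31 of 67 and 59 of 66. A simulated list of 30 genes lowered by 1 log2 unit was found by preset camera in all 4 fits, which also called 1 of 27 unchanged lists for the change with age and 1 of 27 for development. With an estimated correlation its adjusted p was 0.0143 for the genotype effect, 0.24 for the change with age, 0.00603 for development and 0.0278 for the adult comparison. The comparison with random lists was checked on 12000 independent normal values, which were not drawn from the real libraries. There 40 of 40 lists of 30 genes lowered by 0.6 and 39 of 40 unchanged lists were placed as simulated. Library totals ran from 37724575 to 92560511 counts, and 3 counts, taken as the floor of detection per library, corresponded to a median cRPKM between 0.0163 and 0.0385. Reads carried no molecular identifiers, so floors cover counting error only.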

Results

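Gene expression was measured by RNA sequencing in the eyes of zebrafish with a mutated eMIC domain of srrm3. The gene encodes a splicing regulator of the serine/arginine repetitive matrix family, whose eMIC domain drives the inclusion of neuronal microexons. Mutant and WT sibling eyes were sampled at 48, 60 and 72 hpf and at 5 dpf, with 1 library per genotype and stage, beside 1 library of WT heads at 24 hpf and 2 of WT adult retinae. Totals ranged from 37724575 counts for 72 hpf WT eyes to 92560511 for adult replicate 2. The 5 dpf mutant and WT libraries held 90039615 and 72300388, and the 6 libraries from 48 to 72 hpf 37724575 to 45570408. Across genes, log2 values of siblings correlated at 0.989, 0.984 and 0.986 at 48, 60 and 72 hpf and at 0.940 at 5 dpf, and those of the adult replicates at 0.917. Genes are not independent replicates in these correlations.

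The transcript of srrm3 was found in every library. Its cRPKM was 0.18 in the 24 hpf head. In mutant and WT eyes it was 1.76 and 1.09 at 48 hpf, 2.36 and 2.06 at 60 hpf, 2.64 and 1.26 at 72 hpf, and 3.30 and 4.15 at 5 dpf, and it was 2.66 and 4.24 in the adult retinae. The log2 fold change of srrm3 between genotypes was 0.24 ± 0.27, with an adjusted p of 0.895 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so its level does not separate the genotypes. The mutation alters a domain and need not change the transcript level, which makes this a weak check of the labels. srrm4, the paralog that also carries an eMIC domain, had a log2 fold change of −0.11 ± 0.24 and an adjusted p of 0.940.

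The first comparison asked which genes differed between mutant and WT eyes over all 4 stages. By preset camera the rod, cone, lens and ribosomal protein lists were lower and the skeletal muscle list higher in mutant eyes, and 1 single gene passed its test. None of these lists passed with an estimated correlation (adjusted p = 0.716 for each) or by fry, and each had a median of the opposite sign in at least 1 of the 4 sibling pairs. The list of rod phototransduction and disc genes had a median log2 fold change of −0.94, with 21 of 22 members lower, and the cone phototransduction list −0.85, with 26 of 30 lower. By camera with the preset correlation their adjusted p were 9.0e-07 and 1.8e-07, and both had an adjusted p of 0.716 with an estimated correlation. No member of either list passed edgeR's test, neither over all genes tested nor adjusted over the list alone. NR2E3, a rod transcription factor gene, stood at −0.13 ± 0.13 (adjusted p = 0.887). Among cone genes pde6ha, which encodes an inhibitory subunit of the cone phosphodiesterase, stood at −2.004 ± 1.224, PDE6H at −1.75 ± 0.80, opn1lw1 at 0.47 ± 0.27 and opn1mw2 at 0.11 ± 0.13. The 5 dpf pair carried most of this: without it the list medians were −0.19 for rods and −0.30 for cones.

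The fitted change was negative for all 51 lens genes tested, with a median of −0.39 (camera adjusted p = 2.2e-19, and adjusted p = 0.716 with an estimated correlation). Of these 18 fell when adjusted over the list alone and 0 over all genes tested. The γM-crystallin genes crygm2d3 and crygm2d16 stood at −0.84 ± 0.12 and −0.90 ± 0.14, each lower in 4 of 4 pairs, with an adjusted p of 0.506 by edgeR's quasi-likelihood test. crygm2d4 stood at −0.87 ± 0.18, crygm2d10 at −0.68 ± 0.11, and crybb1l3 and crygm1 at −0.07 ± 0.16 and −0.08 ± 0.70. By DESeq2 crygm2d3, crygm2d16, crygm2d10 and crygm2d4 passed, with adjusted p of 7.2e-06, 1.2e-05, 1.0e-05 and 0.00318. The lens median was −0.25 without the 5 dpf pair, and in the 72 hpf pair alone 31 of 45 lens genes were higher in the mutant. Other genes lower in 4 of 4 pairs that did not pass edgeR's test were CKMT2 ENSDARG00000069615, a mitochondrial creatine kinase gene, at −1.59 ± 0.24 (adjusted p = 0.691, but 5.2e-08 by DESeq2 and 0.0217 without the 72 hpf pair), and kcnh7, a potassium channel gene, at −0.84 ± 0.13 (adjusted p = 0.538).

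The skeletal muscle list had a median of 0.68, with 41 of 46 members higher (camera adjusted p = 4.5e-15, and adjusted p = 0.716 with an estimated correlation). Adjusted over the list alone 9 members rose, and over all genes tested 0 did. The fast myosin heavy chain genes myhz1.2 and myhz1.3 stood at 1.32 ± 0.30 and 1.201 ± 0.274, while tnnc2.1 stood at −0.45 ± 0.17 and TNNI2 ENSDARG00000005841 at −0.19 ± 0.10. Muscle genes also had the lowest p-values among those higher in 4 of 4 pairs, without passing edgeR's test: RYR1 ENSDARG00000023797 at 0.78 ± 0.15, TTN ENSDARG00000000563 at 0.70 ± 0.14, TTN ENSDARG00000028213 at 0.64 ± 0.13, NEB at 0.70 ± 0.14 and PFKM ENSDARG00000014179 at 0.68 ± 0.15, with adjusted p from 0.744 to 0.881. DESeq2 called RYR1 ENSDARG00000023797, both TTN genes and NEB, with adjusted p from 0.00318 to 0.00745. The list median was 0.79, 1.05, −0.25 and 1.299 in the single pairs from 48 hpf to 5 dpf. Summed Hox genes of groups 4 to 13, which mark the trunk, had log2 ratios of 0.35, 2.28, −0.54 and 3.07 in the same pairs. Ribosomal protein genes had a median of −0.22, with 80 of 81 lower (camera adjusted p = 4.4e-23, and 0.716 as the adjusted p with an estimated correlation). RPL36 and RPL37 stood at −0.44 ± 0.14 and −0.43 ± 0.14, RPL4 at −0.07 ± 0.10 and RPL7L1 at 0.03 ± 0.12, and the single-pair median was positive at 5 dpf (0.33).

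Over all genes, 1 of 21829 was significantly higher and 0 were lower by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 1074 genes, where 1091 would be expected by chance. DESeq2 called 8 higher and 51 lower, and limma on log2 cRPKM called 0. The called gene was ela2l, which encodes a pancreatic elastase, with a log2 fold change of 7.25 ± 0.29 and an adjusted p of 0.0388. Its cRPKM was 439 in mutant and 2.23 in WT eyes at 5 dpf and 0 in the 6 younger eye libraries, so the call rests on 1 of 4 pairs. It was lost by DESeq2 (1.03 ± 3.45, adjusted p = 0.985) and by limma (adjusted p = 0.667 and 0.638). The 59 DESeq2 calls shared none with edgeR, and DESeq2 gave no adjusted p to 12696 genes. Preset camera called 3 lists higher and 11 lower in all, camera with an estimated correlation 0 and fry 0. The remaining lower lists had medians of −0.42 for the photoreceptor ribbon synapse, −0.33 for bipolar cells, −0.22 for visual cycle and pigment epithelium and also for amacrine cells, −0.15 for photoreceptor fate regulators, −0.14 for outer segment structure and cilium and −0.09 for retinal ganglion cells. Cartilage and periocular mesenchyme (0.18) and the unfolded protein and integrated stress response (0.05) were the other higher lists. Their adjusted p with an estimated correlation lay between 0.716 and 0.800.

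**Figure D1:**
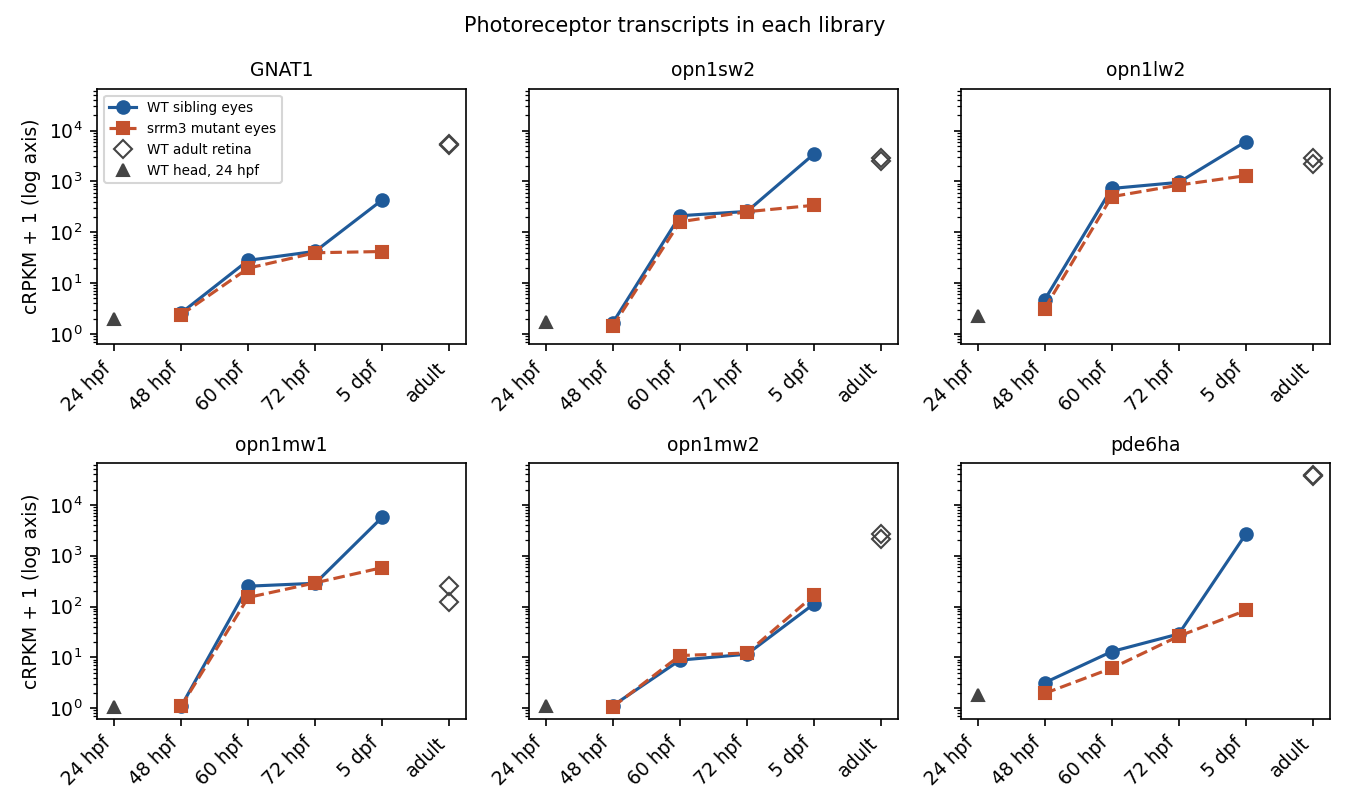
cRPKM + 1 on a log axis for 6 photoreceptor genes against stage, with WT sibling eyes as circles, srrm3 mutant eyes as squares, WT adult retinae as diamonds and the 24 hpf WT head as a triangle, each symbol being 1 library. At 5 dpf GNAT1, opn1sw2, opn1lw2, opn1mw1 and pde6ha lay 4.70-fold to 32.4-fold lower in the mutant, opn1mw2 did not (166 and 112 cRPKM), and the genotypes lay close together at 72 hpf.

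The single sibling pairs show at which stage these groups parted, without any replicate check. At 5 dpf photoreceptor transcripts were far lower in the mutant library. pde6ha had a cRPKM of 82.8 in mutant and 2679 in WT eyes, a 32.4-fold difference, and grk1b, an opsin kinase gene, had 16.96 and 208.96. CLUL1 had 4.62 and 83.4 and TENT5A 2.16 and 32.2. The rod transducin gene GNAT1 (40.85 and 434.6), the blue cone opsin gene opn1sw2 (339 and 3499.9), the green cone opsin gene opn1mw1 (584 and 5761) and the red cone opsin gene opn1lw2 (1300.4 and 6117) were chosen after their values were seen. The opsin genes opn1mw2 (166 and 112) and opn1lw1 (22.7 and 11.3) had the opposite sign. The median log2 ratio was −2.40 for rod genes, with 17 of 22 at least 2-fold lower, and −2.03 for cone genes, with 22 of 29, where matched random lists gave 0.01 to 0.39 and 0.00 to 0.36. The median of all genes was itself 0.21 in this pair, and relative to it the rod and cone medians were −2.61 and −2.24. The ribbon synapse (−0.70), lens (−0.49), bipolar (−0.38), photoreceptor fate (−0.29), amacrine (−0.23), circadian clock (−0.20), outer segment and cilium (−0.19) and retinal ganglion cell (0.01) lists were also below their random lists.

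In the same 5 dpf mutant library pancreatic enzyme transcripts were abundant. ctrb.1, a chymotrypsinogen gene, had 811 cRPKM against 4.49 in WT, CELA1 ENSDARG00000017314 630.2 against 3.71, and the trypsinogen genes prss59.2 and prss59.1 901 against 5.91 and 562 against 3.37. The exocrine pancreas list had a median log2 ratio of 6.65 over 19 genes, liver 1.64 over 18, endocrine pancreas 0.93 over 12 and intestine 0.75 over 9. Higher than their random lists were also skeletal muscle (1.299), microglia and other leukocytes (1.06), cartilage and periocular mesenchyme (0.86), unfolded protein and integrated stress response (0.77), skin (0.67), p53 and apoptosis (0.63), reactive glia (0.60), brain regional patterning (0.42), ribosomal proteins (0.33) and the added list of brain regions (0.73). Of 12560 genes 659 were at least 2-fold higher and 317 lower in the mutant, so 67.5% of these were higher. Centred on the median gene they were 399 and 445, with 47.3% higher.

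**Figure D2:**
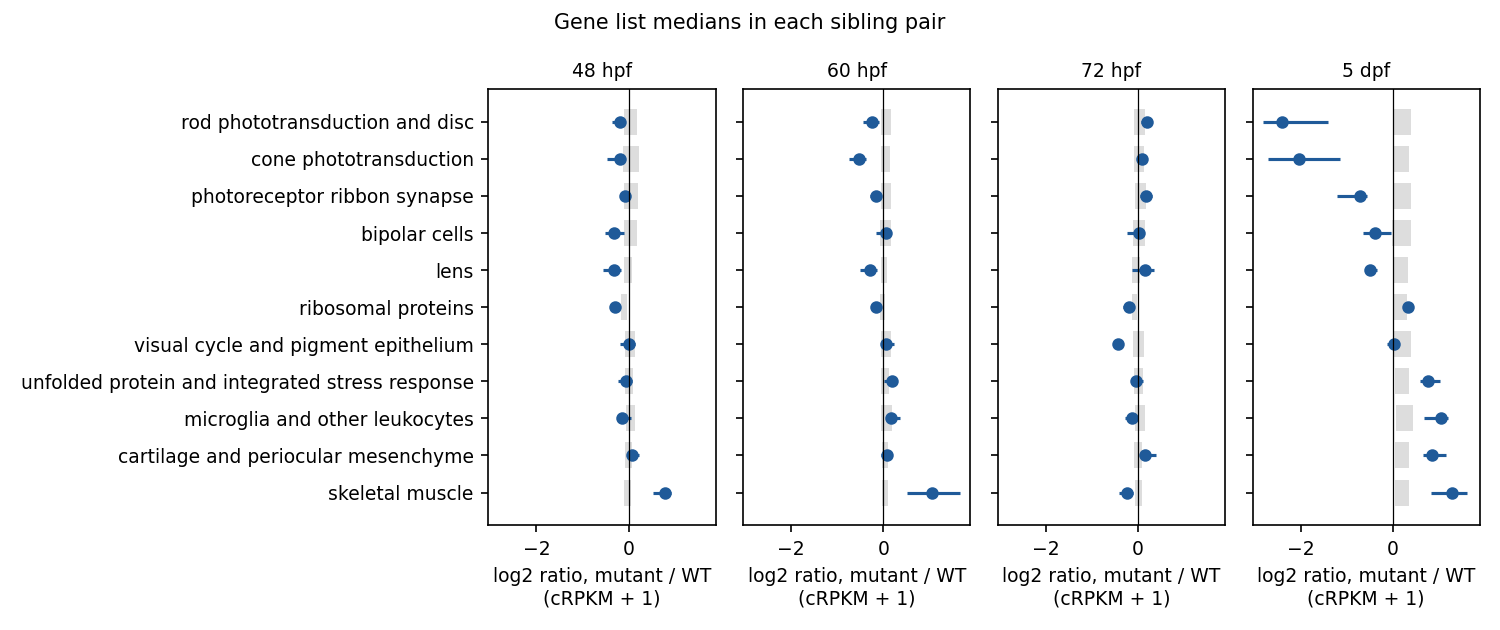
Median log2 ratio of mutant to WT (cRPKM + 1) of 11 gene lists in each sibling pair, as points with bars from the first to the third quartile of the members, and the middle 95% of matched random lists as grey bands. Rod and cone medians lay between −0.52 and 0.19 up to 72 hpf and at −2.40 and −2.03 at 5 dpf, while the skeletal muscle median was above its band at 48 hpf, 60 hpf and 5 dpf and below it at 72 hpf.

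At 48 hpf 55 of 11098 genes were at least 2-fold higher in the mutant and 20 lower. The immediate early gene FOS had a cRPKM of 23.7 in mutant and 4.03 in WT eyes, myhz1.3 78.6 and 21.0, and myhc4 25.2 and 8.14. CYP1A1, a target of the aryl hydrocarbon receptor, had 7.92 and 26.8, tcnbb 294 and 676, and GNB3, a cone transducin subunit gene, 6.95 and 16.9. Skeletal muscle (0.79), heat shock and immediate early genes (0.28), Müller glia (0.15) and circadian clock (0.14) lay above their random lists, and bipolar (−0.32), lens (−0.31), ribosomal protein (−0.29), cone (−0.19), rod (−0.19), photoreceptor fate (−0.15), microglia and leukocyte (−0.14), amacrine (−0.12) and retinal ganglion cell (−0.08) genes below them. Of the added lists Hox (0.29) and liver (0.20) lay above, and endocrine pancreas (−0.26) and brain regions (−0.15) below. At 60 hpf 147 of 11203 genes were higher and 31 lower. The fast muscle gene MYL11 ENSDARG00000002589 had 309 cRPKM in mutant and 28.4 in WT eyes, while fabp10a, a liver fatty acid binding protein gene, had 2.31 and 22.4, and uox, a urate oxidase gene, 1.81 and 7.20. RRM2 ENSDARG00000020711, a ribonucleotide reductase gene, had 0 counts in mutant and 43 in WT eyes. Muscle (1.05), blood (0.76), p53 and apoptosis (0.21), unfolded protein response (0.20), skin (0.18) and brain regional patterning (0.15) medians lay above their random lists, as did the added Hox (1.62), liver (0.57) and intestine (0.29) lists. Those of cone (−0.52), lens (−0.29), rod (−0.24), ribbon synapse (−0.16), ribosomal protein (−0.16), progenitor (−0.11), neuronal splicing regulator (−0.03) and outer segment and cilium (−0.01) genes lay below, as did 3 exocrine pancreas genes (−0.45).

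At 72 hpf the pair had 29 genes at least 2-fold higher and 37 lower of 11730. and3 and and2, actinodin genes of the fin fold, had 1.22 and 1.92 cRPKM in mutant against 14.4 and 17.6 in WT eyes, and uox 6.31 against 1.70. All 22 visual cycle and pigment epithelium genes were lower in the mutant, with a median of −0.43. Photoreceptor fate regulators (0.30), outer segment structure and cilium (0.27), neuronal splicing regulators (0.25), progenitors (0.24), amacrine cells (0.19), rod genes (0.19), circadian clock (0.18), ribbon synapse (0.18), lens (0.16) and cartilage (0.16) had medians above their random lists, in several cases opposite in sign to the earlier pairs. Skeletal muscle (−0.25), skin (−0.21), ribosomal proteins (−0.199), Müller glia (−0.19), microglia and other leukocytes (−0.13) p53 and apoptosis (−0.08) and the added Hox list (−0.41) also lay below theirs. The remaining genes named by their ratios at 48 to 72 hpf, among them TOR4A ENSDARG00000010145, znf1133, znf1082, znf1050, snord31.1 and 5S_rRNA genes, rested on 14 counts or fewer in either library and are given no fold.

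Whether the genotype effect changed with age was tested over the 8 eye libraries. The mutant to WT ratio fell with age for NXNL1, SLC6A5 and 26 other genes, and it rose for genes that include the proteases ctrb.1, ctrb.2 and prss59.2. The glycine transporter gene SLC6A5 fell by 4.61 ± 0.54 log2 units per doubling of age (adjusted p = 0.0227 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), the kinase gene camkk1b by 2.99 ± 0.47 (0.0262) and the opsin gene opn6b by 2.98 ± 0.44 (0.0168). NXNL1, which encodes the rod-derived cone viability factor, fell by 2.67 ± 0.40 (adjusted p = 0.0158), nim1kb by 2.63 ± 0.37 (0.0130) and marchf1 by 2.60 ± 0.44 (0.0262). SLC6A5 stood at 0.10 cRPKM in mutant and 3.95 in WT eyes at 5 dpf, NXNL1 at 7.12 and 45.2, and camkk1b at 3.83 and 31.2. In adult retina replicates 1 and 2 SLC6A5 stood at 0.02 and 0.03, NXNL1 at 23.19 and 27.47, and camkk1b at 25.98 and 62.55. The tissue of origin of the SLC6A5 transcripts was not tested. Without the 5 dpf pair the slopes of camkk1b and opn6b turned to 0.093 and 0.183. Those of SLC6A5, NXNL1, nim1kb and marchf1 shrank to −2.59, −0.86, −0.90 and −1.33. The 6 largest rises were ctrb.2, tcnba, c6ast4, prss59.2, CELA1 ENSDARG00000017314 and ctrb.1, with adjusted p from 6.9e-07 to 0.0130, and 5 dpf mutant levels between 101 (tcnba) and 901 cRPKM (prss59.2). By DESeq2 ctrb.2, c6ast4 and ctrb.1 (adjusted p = 0.9998 each) and prss59.2 (0.0640) did not pass, and by limma at a pseudocount of 1 none of the falls or rises named here that it tested did (adjusted p from 0.349 to 0.466).

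Of the rod genes 0 changed over all genes tested, and 1 rose and 7 fell adjusted over the list alone, with a median slope of −2.11 (camera adjusted p = 2.2e-10, and adjusted p = 0.737 with an estimated correlation). Cone genes had a median of −1.78, with 8 falls adjusted over the list alone and 0 over all genes (camera adjusted p = 2.2e-10, and again an adjusted p of 0.737 with an estimated correlation). PDE6B ENSDARG00000011671 stood at −3.19 ± 0.79, NR2E3 at −0.36 ± 0.25, pde6ha at −3.81 ± 1.69, opn1mw1 at −3.15 ± 0.93, opn1lw1 at 0.68 ± 0.76 and opn1mw2 at 0.18 ± 0.30, and none of these passed edgeR's test in log2 hours. With hours as a linear term PDE6B ENSDARG00000011671 passed (adjusted p = 0.0335). The microglia and leukocyte list had a median of 0.75, with 3 rises adjusted over the list alone and 0 over all genes (camera adjusted p = 5.8e-07, and adjusted p = 0.737 with an estimated correlation). The chemokine gene ccl34b.1 stood at 1.59 ± 0.40 and lyz, encoding lysozyme, at 1.46 ± 0.31, while tnfb and MFAP4 ENSDARG00000038681 stood at 0.00 ± 0.44 and 0.10 ± 0.62. The unfolded protein and integrated stress response list had a median of 0.47, with 7 rises adjusted over the list alone and 0 over all genes (camera adjusted p = 1.5e-06, and 0.737 as the adjusted p with an estimated correlation). Its transcription factor genes atf5a and ATF3 stood at 2.12 ± 0.43 and 1.17 ± 0.98, and slc7a11 and DNAJB9 ENSDARG00000052072 at −0.49 ± 0.44 and −0.22 ± 0.37. By DESeq2 atf5a (adjusted p = 7.3e-05), lyz (0.00913) and ccl34b.1 (0.0382) passed, as they did with hours as a linear term. At 5 dpf atf5a had 92.85 cRPKM in mutant and 13.6 in WT eyes, and ATF3 43.1 and 6.20. That mutant library also held pancreas and liver transcripts. Whether the leukocyte and stress response rises came from such tissue or from the eye was not tested.

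In all 49 genes rose and 28 fell with age in the mutant to WT ratio, of 21829 tested, and 6 lists were called higher and 9 lower by preset camera, 0 with an estimated correlation and 0 by fry. Without the 5 dpf pair edgeR called 0 genes (494 at an unadjusted p under 0.05), and the rod and cone list medians turned to 0.74 and 0.97, both passing preset camera in that direction (adjusted p = 1.0e-05 and 0.00113). DESeq2 called 124 rises and 167 falls, and limma on log2 cRPKM with a pseudocount of 1 called 0. On simulated counts the edgeR fit made false calls above its nominal rate. The 5 dpf pair also belongs to the other library set and its mutant library held the pancreatic transcripts.

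**Figure D3:**
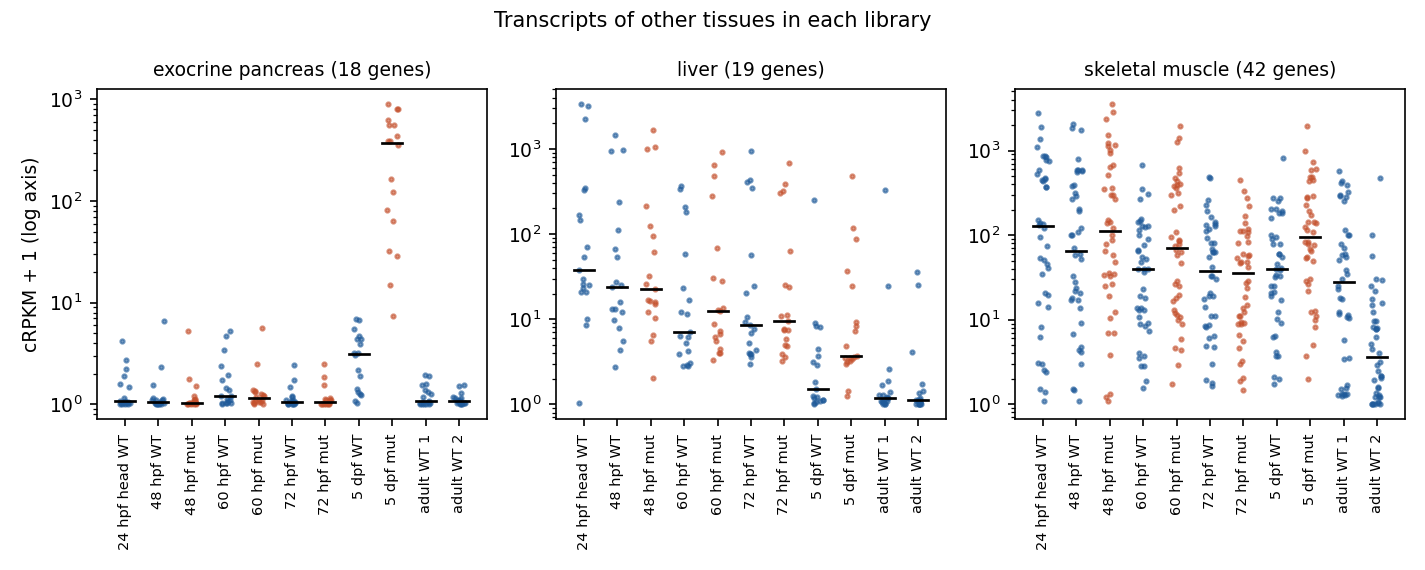
cRPKM + 1 on a log axis of exocrine pancreas, liver and skeletal muscle genes in each of the 11 libraries, where each point is 1 gene, mutant libraries are orange, WT libraries blue, and the line is the median over genes. Exocrine pancreas genes were high in the 5 dpf mutant library alone.

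Developmental change was tested as the slope per doubling of age from 48 hpf to 5 dpf, both genotypes together. Siblings of an age counted as independent libraries, so the p-values can be too small. Genes of photoreceptors, bipolar cells, lens and the circadian clock rose, and genes of proliferation and brain patterning fell. Of 30 cone genes 25 rose and of 22 rod genes 15 rose, with medians of 4.46 and 3.40 (camera adjusted p = 5.1e-11 and 9.4e-06, and adjusted p = 0.477 and 0.585 with an estimated correlation). Adjusted over the list alone 29 and 18 rose. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment pde6ha rose by 6.92 ± 0.84 (adjusted p = 0.00114), guca1c, a guanylate cyclase activator gene, by 6.24 ± 0.58 (0.000534), PDE6H by 5.59 ± 0.55 and SLC24A2, a cone sodium and calcium exchanger gene, by 1.88 ± 0.27. opn1lw1 rose from 0 at 48 hpf to 22.7 and 11.3 cRPKM at 5 dpf (adjusted p = 0.000363). Among rod genes cngb1a rose by 4.45 ± 0.75 (adjusted p = 0.00354) and rom1a by 4.66 ± 1.11 (0.0137), while gnb1b stood at 0.14 ± 0.24. Of 18 bipolar genes 11 rose, 12 adjusted over the list alone, with a median of 1.90 (adjusted p = 0.477 with an estimated correlation). NYX, encoding nyctalopin, rose by 4.73 ± 0.80 and TRPM1, the channel of ON bipolar cells, by 2.57 ± 0.35, whereas VSX1 stood at 0.24 ± 0.53.

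Of 51 lens genes 27 rose, 36 adjusted over the list alone, with a median of 1.71 (adjusted p = 0.477 with an estimated correlation). crygm7 rose by 5.96 ± 0.46 and the connexin gene GJA3 by 1.45 ± 0.27, and pitx3 stood at 0.20 ± 0.16. Of 39 clock genes 24 rose and 2 fell over all genes tested, and 25 rose and 2 fell adjusted over the list alone, with a median of 1.31 (adjusted p = 0.477 with an estimated correlation). NR1D1, a nuclear receptor gene of the clock, rose by 5.68 ± 0.78, nfil3-6 by 3.82 ± 0.15 and dbpb by 4.34 ± 0.39, and bmal2 fell by 1.23 ± 0.20. The time of day of sampling is not given in the sources used here. Of 38 progenitor and proliferation genes 30 fell and 2 rose, with the same counts adjusted over the list alone and a median of −1.20 (adjusted p = 0.477 with an estimated correlation). The mitotic genes CDC20, aurka, CCNB1 and plk1 fell by 1.77 ± 0.13, 1.75 ± 0.14, 1.65 ± 0.15 and 1.45 ± 0.14, while the retinal homeobox gene rx1 rose by 1.47 ± 0.29 and RRM2 ENSDARG00000020711 by 2.38 ± 0.74, a call lost without the 5 dpf pair (0.78 log2 units, adjusted p = 0.836) and under 3 other alternatives (0.136 to 0.277). Of 53 brain patterning genes 41 fell, 44 adjusted over the list alone, with a median of −1.35 (adjusted p = 0.162 with an estimated correlation). The hindbrain gene HOXB2 fell by 2.39 ± 0.25, ascl1b by 2.26 ± 0.17 and hoxb1b by 3.35 ± 0.51. Trunk Hox genes of groups 4 to 13 and hatching enzyme genes fell over the same ages, from a summed Hox cRPKM of 206 and 162 at 48 hpf to 15.05 and 1.79 at 5 dpf. The eye libraries thus also differed in transcripts of genes that mark tissues outside the eye. The tissue of origin of these transcripts was not tested.

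The largest falls with age were of the hatching enzyme genes he1.1 and he1.2, the embryonic globin gene hbbe3, afp4 ENSDARG00000041490, HOXC6 ENSDARG00000101954 and HOXB9. he1.1 went from 186 and 180.1 cRPKM in mutant and WT eyes at 48 hpf to 0 at 5 dpf (adjusted p = 0.00117), and hbbe3 from 601 and 654 to 0 and 0.06 (adjusted p = 0.00237). The largest rises were ela2l, ctrb.2, c6ast4 and ctrb.3, present mainly in the 5 dpf mutant library, with gig2l (14.2 and 3.97 cRPKM at 5 dpf and 0 before) and grna.2, a granulin gene (19.9 and 18.1 at 5 dpf). srrm3 rose by 0.99 ± 0.30 per doubling of age (adjusted p = 0.0333), and srrm4 stood at −0.01 ± 0.27. Over all genes 4157 rose and 3983 fell of 21829 tested, and preset camera called 8 lists higher and 5 lower, camera with an estimated correlation 0 and fry 13. The other called lists were the ribbon synapse (17 of 21 rose), outer segment structure and cilium (24 of 46), heat shock and immediate early genes (11 of 28), ribosomal proteins (38 of 81 fell), blood (11 of 14 fell) and neuronal splicing regulators (11 of 37 fell), with adjusted p of 0.477 to 0.679 with an estimated correlation. Without the 5 dpf pair 338 rose and 343 fell, and 29 of the gene calls that the naming rule covers were lost, in a fit with fewer libraries. Their slopes kept their sign. Those of rom1a (9.08), cngb1a (7.17), NYX (8.66), crygm7 (6.15), NR1D1 (6.08), rx1 (2.07), CCNB1 (−1.84) and he1.1 (−9.65) were as steep or steeper, and those of srrm3 (0.63), PDE6H (4.49), SLC24A2 (1.37), GJA3 (1.33), dbpb (3.02), bmal2 (−0.50) and hbbe3 (−6.57) were shallower. DESeq2 lost ela2l, ctrb.2, c6ast4, gig2l, ctrb.3, grna.2, he1.1, hbbe3 and afp4 ENSDARG00000041490. Without the 5 dpf mutant library alone, a fit added after the data had been seen, 2357 rose and 1872 fell.

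Adult WT retina was compared with 5 dpf WT eyes, a contrast in which age and dissected tissue differ together. Most rod genes and some cone genes were higher in the adult retina, the opsin gene opn1mw1 was lower, and most lens, pigment epithelium, proliferation and patterning genes were lower. Of 22 rod genes 19 rose and 1 fell, also adjusted over the list alone, with a median of 4.05 (camera adjusted p = 8.2e-07, and adjusted p = 0.897 with an estimated correlation). The fitted 5 dpf level also drew on the mutant library, where most rod and cone genes were lower than in WT. The fitted rises of these lists can therefore exceed the plain adult to WT rises. PDE6B ENSDARG00000000380, a rod phosphodiesterase gene, went from 51.5 cRPKM in 5 dpf WT eyes to 771 ± 331 (SD, n = 2), PDE6G from 190.0 to 2279 ± 21.0 and SLC24A1 from 5.61 to 87.9 ± 1.71. Their adjusted p were 0.0122, 0.00414 and 0.00226 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The PDE6B ENSDARG00000000380 call was lost without adult replicate 2 (adjusted p = 0.0637). rcvrna had 528 cRPKM in the eyes and 538 ± 78.5 (SD, n = 2) in the retina. Of 31 cone genes 14 rose and 1 fell, 16 and 1 adjusted over the list alone, with a median of 1.71 (adjusted p = 0.897 with an estimated correlation). The green opsin gene opn1mw1 fell from 5761 to 187 ± 88.2 cRPKM (SD, n = 2; adjusted p = 0.0210). opn1mw2 rose from 112 to 2373 ± 400.2, opn1mw3 from 0.41 to 596 ± 36.9, opn1mw4 from 0.06 (4 counts) to 340.3 ± 85.4 and the red opsin gene opn1lw1 from 11.3 to 1298 ± 172 (SD, n = 2). The opn1mw1 call was lost without either adult replicate, where the lone adult library is assumed to vary like the other groups.

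Of 53 lens genes 47 fell and 2 rose, 48 and 2 adjusted over the list alone, with a median of −11.95 (adjusted p = 0.349 with an estimated correlation). LIM2 ENSDARG00000015445 had 901 cRPKM in 5 dpf WT eyes and 1 and 3 counts in the adult retinae, crygm2d15 had 5580.4 cRPKM and 2 and 5 counts, and lim2.3 had 346 cRPKM and 1 count in each. Further crystallin genes among the 6 largest falls were crygm2d7, crygm2d10 and crygm2d4, and pitx3 and lim2.2 did not pass, though pitx3 did without adult replicate 1 or replicate 2 (adjusted p = 1.1e-05 and 0.0124). Of 23 visual cycle and pigment epithelium genes 22 fell, also adjusted over the list alone, with a median of −3.88 (adjusted p = 0.349 with an estimated correlation). The melanin synthesis genes TYR, DCT and TYRP1 ENSDARG00000029204 fell by 8.25 ± 0.56, 5.93 ± 0.28 and 4.71 ± 0.18, and the retinal G protein-coupled receptor gene RGR by 1.51 ± 0.38, a call lost without the 5 dpf mutant library (adjusted p = 0.0503). Of 39 progenitor and proliferation genes 32 fell and 1 rose, 32 and 2 adjusted over the list alone, with a median of −3.52 (adjusted p = 0.536 with an estimated correlation). The mitotic genes kif11, bub1 and plk1 fell by 6.02 ± 0.60, 5.96 ± 0.54 and 5.85 ± 0.20, her4.1 fell by 4.73 ± 0.28, and rx1 rose by 1.99 ± 0.36.

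The largest rises included the globin gene HBE1 ENSDARG00000089087, at least 3502-fold and 743-fold higher in adult replicates 1 and 2 than the 3-count floor of the 5 dpf WT library, HBE1 ENSDARG00000069734, at least 665-fold and 119.5-fold, and the complexin gene CPLX4 ENSDARG00000059486, at least 384-fold and 584-fold. gatd3l rose from 1.03 to 3665 ± 1082 cRPKM, and mhc1uba, a major histocompatibility gene, from 0.06 to 527.8 and 70.5 in replicates 1 and 2. The replicates differed in other tissues: set against replicate 2, replicate 1 had median log2 ratios of 3.50 for skin (26 of 26 genes higher), 2.98 for skeletal muscle (34 of 36), 1.88 for microglia and other leukocytes (28 of 28), 1.70 for blood (8 of 9), 1.66 for cartilage and 1.34 for ribosomal proteins, and −0.31 for rod genes. Changes of globin, histocompatibility and these lists therefore vary widely between the 2 adult libraries. srrm3 stood at 3.45 ± 1.12 cRPKM (SD, n = 2) in the retina and 4.15 in the eyes (adjusted p = 0.491), and srrm4 at 0.94 ± 0.59 and 2.61 (adjusted p = 0.260, but 0.0135 without adult replicate 2). Preset camera called 4 lists higher and 8 lower, camera with an estimated correlation 0 and fry 11. The other higher lists were outer segment structure and cilium (0.86) and the ribbon synapse (1.15). The other lower lists were brain regional patterning (−2.63, or −2.45 with members at 0 in a group set to their bound), cartilage (−2.37), ribosomal proteins (−0.80), skeletal muscle (−0.65) and skin (−0.51). Patterning had an adjusted p of 0.081 with an estimated correlation and the rest 0.897. Over all genes 4073 rose and 3853 fell of 23235 tested, so that 51.4% were higher. limma on log2 cRPKM gave 2515 and 5270, with 32.3% higher and an all-gene median shift of −0.26. The fit without the 5 dpf mutant library gave 2270 and 2688, and that without adult replicate 1 gave 5581 and 6267.

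The WT head at 24 hpf, set against WT eyes at 48 hpf, differed in both tissue and age, with 1 library each and no replicate check. Genes of lens, photoreceptors and retinal neurons were lower in the head, and progenitor genes higher. crx, a photoreceptor transcription factor gene, had 2.05 cRPKM in the head and 46.2 in the eyes, crygm2d15 9.72 and 179.8, fgfbp2b 127 and 2947 counts, and COL10A1 ENSDARG00000054753 4 and 1693 counts. afp4 ENSDARG00000041490 had 569 in the head and 51.7 in the eyes, and actc1c, a cardiac actin gene, 97 counts and 1. List medians were −1.65 for lens, −1.52 for rods, −1.18 for photoreceptor fate regulators and also for the ribbon synapse, −1.09 for bipolar cells, −0.86 for retinal ganglion cells and −0.83 for cones, and 22 of 22 amacrine genes were lower. Visual cycle and pigment epithelium (0.01), Müller glia (0.16), horizontal cells (−0.38) and outer segment and cilium (−0.33) lay inside their random lists. Below theirs were also circadian clock (−0.71), microglia (−0.66), neuronal splicing regulators (−0.65), vascular endothelium (−0.48), unfolded protein response (−0.45) and cartilage (−0.43). Progenitor (0.67), blood (0.59), muscle (0.47) and brain regional patterning (0.12) genes had higher medians in the head than their random lists. Of 11096 genes 405 were at least 2-fold higher in the head and 995 lower.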

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

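The delay test and the split tests were written before the result they bear on was seen, and the liver, dilution and Hox tests only after. The single genes and gene lists given first stand out because the genotype effect differed between ages, by a test of that difference over the 8 eye libraries. The mutant to WT ratio rose with age for 49 genes and fell for 28. The 6 largest rises per doubling of age were ctrb.2 (log2 change 14.64), tcnba (12.72), c6ast4 (11.43), prss59.2 (10.06), CELA1 ENSDARG00000017314 (9.36) and ctrb.1 (9.16). These fitted values depend on libraries with counts at or near 0, and the 5 dpf levels are the surer measure. The 6 largest falls were SLC6A5 (−4.61), camkk1b (−2.99), opn6b (−2.98), NXNL1 (−2.67), nim1kb (−2.63) and marchf1 (−2.60).

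Among gene lists the median change of the genotype effect per doubling of age was −2.11 for rod genes, −1.78 for cone genes, −0.83 (−0.835) for the ribbon synapse, −0.49 for the circadian clock, −0.35 for lens, −0.34 (−0.342) for outer segment and cilium, −0.34 (−0.338) for bipolar cells, −0.30 for visual cycle and pigment epithelium and −0.27 for amacrine cells. It was 0.75 for microglia and other leukocytes, 0.47 for the unfolded protein and integrated stress response, 0.42 for cartilage and periocular mesenchyme, 0.35 for skin, 0.31 for p53 and apoptosis and 0.25 (0.245) for ribosomal proteins. All 15 lists passed by preset camera and none with an estimated correlation, where each adjusted p was 0.737.

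Chance was weighed by regrouping the 8 eye libraries into 2 sets of 4 in every way that could be fitted, 32 in all. For the change with age 19 of the 32 groupings, the real one included, had at least the 77 genes called for genotype, and the highest had 2048. For the genotype effect 19 of the 32, the real one included, had at least its 1 gene, and the highest had 50. Among the 8 groupings that separate every sibling pair the counts were 7 for each, with other groupings reaching 667 and 3 genes. With 8 groupings no share under 0.125 can be reached, and each keeps the 5 dpf difference with its labels kept or flipped, so these 8 decide nothing. The other fitted groupings kept the 5 dpf siblings together or parted them. Those that kept them together called 0 genes in both tests. Those that parted them and 1 younger pair called 379 to 2048 genes for the change with age and 3 to 50 for genotype. The 32 groupings therefore mostly record whether the 5 dpf difference is kept, and they measure no chance level. Chance stays not excluded for either set of calls. The highest counts came from groupings that parted the 5 dpf pair and 1 younger pair. Beyond this, why they called far more genes than genotype was not tested. Groupings that separate every sibling pair are balanced for age.

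Lower photoreceptor transcripts at 5 dpf might come from dilution of eye RNA by other tissue. Dilution alone would lower lens and bipolar genes as much as photoreceptor genes, yet the lower of the first quartiles of the lens and bipolar lists was −0.646, while the third quartiles of the rod and cone lists were −1.413 and −1.144. A general delay of the mutant, which could itself follow from genotype, was the other reading. It was weighed on genes at least 4-fold higher in WT at 5 dpf than at 72 hpf. Those in no photoreceptor list had reached a median fraction of 0.657 of that log2 difference in the mutant, over 448 genes. The fraction was 0.192 over 41 rod and cone genes. The quartiles argue against dilution for the whole of the difference. The fractions go against a delay shared alike by all genes, with limits. Both 5 dpf libraries belong to another library set than the 72 hpf one. Genes raised by the set, or in the mutant by other tissue, would reach a high fraction under a delay too. The fractions also assume that both gene groups rise over the same ages. A partial delay or dilution stays open. Genotype is the biological explanation that the design offers, but with 1 pair at this stage it was not tested apart from the library, nor was loss of photoreceptor cells told apart from less transcript per cell.

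Digestive enzyme transcripts in the 5 dpf mutant library may be RNA from abdominal organs. Such carry-over would bring liver transcripts too, and the median log2 ratio of the liver list was 1.642, above its matched random lists (0.083 to 0.492), with 18 of 18 genes higher. The liver list also lay above its random lists at 48 hpf (0.2) and 60 hpf (0.566), but not at 72 hpf (0.062). At 60 hpf the median of 3 exocrine pancreas genes was −0.446, so a raised liver list is not specific to raised pancreatic enzymes. The 5 dpf liver value fits carry-over of abdominal tissue and does not prove it. Expression of these enzymes in the mutant eye itself was not tested.

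Higher muscle transcripts in mutant eyes had no significant trend with age (median slope 0.12, camera adjusted p = 0.468), but the medians of the 4 pairs varied and turned sign at 72 hpf. The explanation tested for them was trunk tissue taken with the eyes. The summed Hox ratio had the sign of the muscle median in 4 of 4 pairs, including the 72 hpf pair, where both were negative. The match fits a dissection difference, though 4 pairs with 1 library per genotype each cannot exclude an effect of genotype.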

How the results depend on the processing

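The tests without the 5 dpf mutant library, and the list tests of age terms without the 5 dpf pair, were chosen only after the results were seen. Among the results for single named genes under the alternatives, those of the genotype effect kept direction and side of the threshold in 324 cases, with 20 reversed, 10 stronger and 7 weaker. The change of the genotype effect with age gave 151 the same, 13 reversed, 8 stronger and 35 weaker, developmental change 502, 11, 0 and 73, and the adult comparison 452, 4, 5 and 5. The cause was not tested for any change below, apart from those made by fewer genes or fewer libraries. No paired analysis beyond the stage factor was possible because only the adults carry replicate numbers.

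With an estimated correlation 0 lists were called higher and 0 lower in each of the 4 fits. For the genotype effect the adjusted p of the rod list ran from 5.4e-14 to 0.716 over the alternatives, cone from 4.7e-19 to 0.716, lens from 8.2e-33 to 0.716, muscle from 1.6e-25 to 0.716 and ribosomal proteins from 4.2e-38 to 0.716.

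For the genotype effect DESeq2 called 8 genes higher and 51 lower. Without a filter 3 were higher, and 0 with a mean cRPKM of at least 5, by limma at either pseudocount, without the stage factor, with log2 hours as a linear term and with the spread estimated over all 11 libraries. The stronger cases were 9 named genes by DESeq2 and CKMT2 ENSDARG00000069615 without the 72 hpf pair, and the weaker ones were all ela2l. limma also moved the median of all genes to 0.10 and 0.12 at pseudocounts of 1 and 0.1. Leaving out 1 pair gave 0 to 2 genes higher, 0 to 3 lower, 1 to 5 lists higher and 8 to 14 lower. Reversed were crygm1 (0.303 by DESeq2, 0.09 and 0.355 by limma, 0.198 with log2 hours as a linear term and 0.182 over all 11 libraries), srrm4 (0.028 and 0.045 by limma), NR2E3 (0.015 and 0.015), crybb1l3 (0.068 and 0.078), RPL4 (0.078 and 0.078), and RPL7L1 without the stage factor (−0.021). Leaving out the 60 hpf pair reversed srrm4 (0.031), the 72 hpf pair srrm3 (−0.012) and the 5 dpf pair the others that follow. Over the 4 fits srrm4 ran from −0.371 to 0.069, srrm3 from −0.012 to 0.563, NR2E3 from −0.251 to 0.015, crybb1l3 from −0.221 to 0.1 and RPL7L1 from −0.067 to 0.127. The median of outer segment and cilium ran from −0.309 to 0.018 and that of the unfolded protein response from −0.058 to 0.164.

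For the change of the genotype effect with age DESeq2 called 124 rises and 167 falls, no filter gave 99 and 70, a mean cRPKM of at least 5 gave 9 and 3, limma 0 and 0 at a pseudocount of 1 and 1 and 0 at 0.1, with all-gene medians of 0.15 and 0.18, and hours as a linear term 167 and 193. Without the 5 dpf pair 0 rose and 0 fell, and 7 lists were higher and 4 lower. That fit has fewer libraries and a shorter span of age. It reversed camkk1b (0.093), opn6b (0.183), srrm4 (0.942), srrm3 (0.542), NR2E3 (0.617), PDE6B ENSDARG00000011671 (0.382), pde6ha (2.003), opn1mw1 (1.783), ATF3 (−2.078) and MFAP4 ENSDARG00000038681 (−0.356). It also reversed the list medians of rods (0.736), cones (0.968), outer segment and cilium (0.794), ribbon synapse (0.624), bipolar cells (0.609), amacrine cells (0.634), p53 and apoptosis (−0.061), lens (0.864) and skin (−0.121). Of these the rod (adjusted p = 1.0e-05), cone (0.00113), outer segment (1.0e-05), ribbon synapse (1.8e-05), amacrine (0.00511) and lens (3.6e-11) lists passed preset camera in the reversed direction. tnfb, near 0, stood at −0.028 by DESeq2, −0.03 with RLE size factors and −0.01 with linear hours. Of the 12 genes named for their change with age limma at a pseudocount of 1 lost the 11 that it tested, DESeq2 lost ctrb.2, c6ast4, prss59.2 and ctrb.1, and a mean cRPKM of at least 5 lost c6ast4, NXNL1 and marchf1. Over the alternatives the adjusted p of the rod list ran from 6.8e-21 to 0.737, cone from 1.5e-21 to 0.737, and microglia and the unfolded protein response reached 0.922.

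For developmental change a mean cRPKM of at least 5 gave 2259 rises and 1910 falls among fewer genes. Fewer libraries gave 338 and 343 without the 5 dpf pair, 1161 and 315 in WT alone, 411 and 133 in mutants alone and 2357 and 1872 without the 5 dpf mutant library. Of the genes called without the 5 dpf pair 476 were also called with it. In WT alone or mutants alone no sibling library counts as a further replicate of an age. Of the named genes 29 lost their call without the 5 dpf pair, 23 in mutants alone, 9 in WT alone and 9 by DESeq2. srrm4 turned positive by DESeq2, RLE size factors and no filter (0.02 each), limma (0.007 and 0.01), WT alone (0.203), linear hours (0.01) and without the 5 dpf mutant library (0.115). Without the 5 dpf pair gnb1b (−0.389) and pitx3 (−0.173) reversed, and in mutants alone gnb1b (−0.271).

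In the adult comparison a mean cRPKM of at least 5 gave 2471 rises and 2161 falls among fewer genes, limma 2515 and 2381 rises at pseudocounts of 1 and 0.1, with an all-gene median of −0.26 and −0.35, and the fit without the 5 dpf mutant library 2270 rises. Leaving out 1 adult replicate gave 4840 to 5581 rises and 5319 to 6267 falls. lim2.2 reversed by limma (−0.205 and −0.312) and without replicate 1 (−0.111), and srrm3 without replicate 2 (−0.077, against 0.762 without replicate 1). Calls were gained for srrm4 without replicate 2 (−1.915) and for pitx3 without replicate 1 (−4.303) or 2 (−0.917).

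In the single pairs a pseudocount of 5 gave 26 genes 2-fold higher and 9 lower at 48 hpf, 80 and 17 at 60 hpf, 15 and 21 at 72 hpf and 290 higher at 5 dpf. A cRPKM of at least 1 gave 136 and 108, 279 and 114, 125 and 126, and 1065 higher. By construction a larger pseudocount shrinks the ratios of low genes and a lower limit admits more of them. Centring gave 399 higher at 5 dpf. Depth limits the 24 to 72 hpf libraries, at 37724575 to 48209161 counts, more than the 5 dpf and adult ones.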

Other observations

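Eye libraries at 48 hpf held transcripts of genes that mark the hatching gland and trunk. he1.1 had 186 and 180.1 cRPKM in mutant and WT eyes and 432.3 in the 24 hpf head, and the 37 summed Hox genes had 206 and 162 cRPKM in mutant and WT eyes, 75.6 and 15.6 at 60 hpf, 23.4 and 34.1 at 72 hpf and 15.1 (15.05) and 1.79 at 5 dpf. The insulin gene ins had 40.9 cRPKM in mutant and 0.10 in WT eyes at 5 dpf, the apolipoprotein gene apoa1b 117 and 7.27, and the trypsinogen gene prss1 811 and 5.82. The stress response gene DDIT3 had 50.2 and 18.5. These 4 genes were chosen after their values were seen.

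Whether a haplotype linked to the mutation carries expression differences was asked by a test of genes near srrm3, written before the result was seen. Of 86 tested neighbours 5.81% had an unadjusted p under 0.05 for genotype, against 4.92% of 21742 other genes (Fisher p = 0.417, 1-sided). Only 98 of 151 neighbours (64.9%) could be matched to measured genes, under a limit of 80% that the written prediction did not state. By the prediction alone the values lay on the side of no excess near srrm3. With so many neighbours unmatched the test is taken as unable to tell. Matching by synonyms was added after a first run and the outcome stayed the same.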
